A study of Mus musculus with 13 samples.

How the data were processed

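The study sequenced RNA of RN2 cells, and 13 samples are described, in the groups shRen (3), shNSD3 (5), shCHD8 (2), sgRosa26 (1) and sgCHD8 (2). By the labels' protocols the hairpins were expressed from a doxycycline-inducible retroviral vector for 48 hours, the guide RNAs were delivered by lentivirus and cells were taken after 4 days, and libraries were made either from polyA RNA with a TruSeq kit or with NSR primers. Per the submitters' processing notes, reads were aligned with TopHat to the mouse genome mm9 and compared with Cuffdiff. The versions are not given in the sources used here.

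The deposited files are 4 tables of the authors' Cuffdiff comparisons, namely shNSD3 against shRen from NSR libraries (9415 genes), an NSD3 table from polyA libraries whose conditions are named only q1 and q2 (7697 genes), shCHD8 against shRen (7800 genes) and sgCHD8 against sgRosa26 (7836 genes). Per the file headers, each row gives a gene, its locus, an FPKM for each of the 2 conditions, a log2 fold, a test statistic (a score with no fixed range), and a p-value, q-value and call by the authors. The FPKM values are deposited as 1 pooled value per condition, so they carry no spread between libraries, and the tables do not say which libraries or how many stand behind them. The authors' deposited p-value equals the 2-sided normal p-value of the test statistic to within 2.75e-06, so the standard error of the log2 fold was taken as the size of the log2 fold divided by the test statistic. This is Cuffdiff's own model of the spread. The deposited test statistic has the opposite sign of the log2 fold in every row, so directions were taken from the FPKM values. The deposited log2 fold was checked against these to within 0.0001.

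The 3 polyA tables list only genes whose first condition had an FPKM above 5, which leaves out genes that were low in the control and rose, while 5638 of the genes of the NSR table lay under 5. In the NSR table the q-values equal a Benjamini-Hochberg adjustment over its rows, and in the polyA tables they do not. Rows with no gene name (1554 in the shCHD8 table and 1679 in the sgCHD8 table) hold nothing and were left out. Gene names that a spreadsheet had turned into dates (16 in the NSR table and 14 in each CHD8 table) were kept as they stand and never named. Of the NSR genes, 19 were listed at 0 in shRen and 1 in shNSD3, and 1 gene was listed at 0 in shCHD8, and none of these entered a fold or a list. A single small RNA, Rnu73b, stood at 385906 FPKM in shRen of the NSR table, out of a sum of 642041 over all genes. Of the 9837 gene names in any table, 9741 (99.0%) matched a GENCODE name of GRCm38, which was used for names only. Coordinates are those of the files, in mm9. Genes that overlap or have near-identical copies are uncertain, since how the authors divided such reads is not given. Total counts per library are not in these tables, so the depth is unknown and no counting interval was computed.

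The design fixed before the data were examined called for limma on log2(FPKM + 1) values of single libraries with a term for the table. As the tables hold pooled values, that fit, its replicate checks and the camera tests of gene lists were replaced by the authors' own calls. A gene counts as called at a q-value under 0.05 in the authors' deposited table. CHD8 results are genes called in both CHD8 tables with the same sign, ranked by the mean of the 2 log2 folds. Differences between tables were tested as the difference of the log2 folds over the root of the summed squared standard errors, as a normal z, with Benjamini-Hochberg adjustment over the shared genes. This treats the tables as independent. Correlations are across genes, and 6 pairs of tables were compared. The tables were normalized separately, so FPKM values are compared within a table. p-values measure only the spread that Cuffdiff estimated. By the labels, the libraries within shNSD3, shCHD8 and sgCHD8 carried different hairpins or guides, so a pooled value may mix reagents and their differences. Nothing says that libraries with the same reagent came from separate cultures, so that part of the spread may be technical.

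The lists fixed in advance, 19 in all, covered Myc targets and ribosome biogenesis, macrophages and monocytes, primary and secondary granules, MLL-fusion targets, the BRD4, NSD and CHD families, DNA replication, mitosis, p53 targets, interferon response, Wnt targets, the integrated stress response, cholesterol synthesis, immediate-early genes, replication-dependent histones, ribosomal proteins, and mast cell, erythroid and lymphoid markers. For each list with at least 5 measured genes the median log2 fold was set against the medians of 10000 random lists matched on mean expression in 10 bins. This describes the tables and is not a test. Calls were also counted with the p-values adjusted over the list alone. Some genes belong to more than 1 list. Named genes are the 12 with the largest rises and the 12 with the largest falls among called genes of each comparison, 5 in each direction for each difference, 12 genes fixed in advance, and up to 4 called genes per list and table, or up to 2 of any members where none was called. Predicted genes and genes known only by a clone or locus number were left out of the first part.

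The difference test and the list percentile were tested on simulated data. With the standard errors of the shCHD8 and sgCHD8 tables (7603 genes, 200 of them changed, 50 repeats), 96.8% of changes of 1 on the log2 scale were recovered and 5.25% of calls were false, against 22.4% and 4.84% for changes of 0.5. For NSR minus q2 over q1 (7405 genes) 28.7% of changes of 1 and 94.3% of changes of 2 were recovered, and for NSR minus shCHD8 (7473 genes) 20.8% and 92.3%. Changes of 0.5 were almost never recovered in these comparisons (0.27% and 0.14%), and of the 33 and 19 calls made there 18.2% and 26.3% were false. Of 100 simulated lists of 25 genes without a shift, between 3% and 6% per table fell outside the middle 95% of random lists, and with a shift of 0.3 between 94% and 100% did. The simulated errors were drawn independently from the standard errors that the test divides by, so the false shares were largely built in. In the deposited tables the robust SD of z was 2.15 for shCHD8 and 2.98 for sgCHD8, where such errors alone would give 1. These rates therefore describe the calculation and not its error or recovery in the real data. Alternatives were pseudocounts of 1 and 0.1, a filter at a mean FPKM of 5, median centring and quantile normalization of each table, with the standard errors kept and q-values recomputed over the rows, and, added after seeing the data, widened standard errors, q-values recomputed over the rows, and only genes with an shRen FPKM of at least 5 in the NSR table. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.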

Results

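RNA was measured by sequencing in 13 libraries of RN2, a mouse acute myeloid leukaemia line that carries the MLL-AF9 fusion and mutant Nras. The series asks what happens to gene expression in these cells when NSD3 or CHD8 is lost. NSD3 (gene Whsc1l1) is a member of the NSD family of histone methyltransferases with a short form that lacks the catalytic domain, and CHD8 is a chromatin remodeller. By the labels, 5 libraries carried hairpins against NSD3 (shNSD3), 2 carried hairpins against CHD8 (shCHD8) and 3 carried the control hairpin against Renilla luciferase (shRen), with 48 hours of induction. A further 2 libraries carried guide RNAs against CHD8 (sgCHD8) and 1 carried a control guide against the Rosa26 locus (sgRosa26), collected 4 days after infection. The deposited data are 4 tables of the authors' own comparisons. Each table gives 1 FPKM value per condition and gene, so no value below has a spread between libraries, and the depth of the libraries is unknown. Errors are the standard errors (SE) of the log2 fold that the authors' test statistic implies. A gene is said to rise or fall where the authors' deposited table called it at a q-value under 0.05.

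The first question of the design is what NSD3 knockdown changes. In the table of shNSD3 against shRen made from NSR libraries, which prime cDNA with a selected set of short primers in place of oligo-dT, Whsc1l1 (mm9 chromosome 8, 26712777 to 26830139) fell from 8.55 to 4.33 FPKM, a log2 fold of −0.98 ± 0.22 in the authors' deposited table. Myc (chromosome 15, 61816895 to 61821916), the transcription factor that drives growth and ribosome production, fell 2.36-fold, from 17.4 to 7.36 FPKM. Genes of neutrophils and macrophages were among those that rose. Cd177, a neutrophil surface protein, rose 5.30-fold from 0.470 FPKM, a fold that rests on a level near 0. It was no longer called with a pseudocount of 1 and its standard error kept, which is largely built in for a gene so low. Olfm4, a protein of a subset of neutrophil granules, rose 3.30-fold and S100a8, a subunit of calprotectin, rose 2.54-fold from 470 to 1193 FPKM. The lysozyme genes Lyz1 and Lyz2 rose 2.14-fold and 2.10-fold, and the chemokine gene Ccl3 rose 2.45-fold.

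The authors' deposited table of the NSR comparison called 28 genes higher and 27 lower among 9415, of which 24 and 19 moved at least 2-fold. The 12 named genes with the largest rises were Car4, Cd177, Stfa2l1, Stfa2, Ptafr, Olfml2b, Olfm4, Lsp1, Gp49a, Serpinb10-ps, Il1rn and Lilrb4, from 7.56-fold for the carbonic anhydrase gene Car4 to 2.71-fold for Lilrb4. The 12 with the largest falls were Bcas1, Snhg9, Spsb4, Stc2, Magoh, Hist2h3c2-ps, Nans, Tnfsf10, Tbcc, Bzw2, Omd and Myc, from 3.93-fold for Bcas1 to 2.36-fold for Myc. Stfa2 and Stfa2l1, and likewise Gp49a and Lilrb4 and the lysozyme genes, are near-identical copies whose reads may have been divided between them, so their separate values are uncertain. Many of these genes were low. Bcas1, Car4 and Cd177 were at 1.63, 0.323 and 0.470 FPKM in shRen. With a pseudocount of 1 and the standard errors kept, their log2 folds shrank from −1.97 ± 0.52, 2.92 ± 0.76 and 2.41 ± 0.50 to −0.89, 1.38 and 1.25, and their calls ended. A pseudocount shrinks every fold, most for low genes, while the standard error stays. Such lost calls show how far a fold depends on low values, and do not weigh the evidence for a change. The calls of Il1rn, Olfml2b, Ptafr, Serpinb10-ps, Spsb4, Stc2 and Tnfsf10, at 0.592 to 6.19 FPKM in shRen, ended as well with smaller folds. Bzw2, Hist2h3c2-ps and Omd were higher, at 8.35, 21.8 and 13.4 FPKM. Their calls, at q-values from 0.0193 to 0.0388 as deposited, ended as the folds went from −1.29 ± 0.35, −1.42 ± 0.37 and −1.25 ± 0.32 to −1.08, −1.31 and −1.12. The median gene of this table stood at −0.15 on the log2 scale. With that shift removed the split was 40 higher and 12 lower, and with quantile normalization it was 42 and 8. Limiting the genes tilted the split the other way, to 24 higher and 41 lower at a mean FPKM of at least 5, and to 22 and 46 at an shRen FPKM of at least 5, a limit added after seeing the data. Under both scalings Bzw2, Hist2h3c2-ps, Omd, Stc2 and Tnfsf10 were no longer called, with log2 folds from −1.47 to −1.10 after scaling, and neither was Bcas1 under the first (−1.82) or Tbcc under the other (−1.13).

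The gene lists fixed before the data were examined moved as follows in the NSR table, where random lists matched on expression lay lower than 0 as well, with typical medians from −0.25 to −0.12. All 52 measured genes of the Myc target and ribosome biogenesis list lay below 0, with a median of −0.63, below each of 10000 random lists. Of these only Myc itself was called in the authors' deposited table, and 13 were called lower when adjusted over the list alone. All 39 replication-dependent histone genes, whose transcripts lack a poly(A) tail, also lay below 0, with a median of −0.64. None was called over all genes, and 13 were called lower when adjusted over the list alone. The macrophage and monocyte list had a median of 0.43 over 24 genes, above each random list, with Lyz1 and Lyz2 called higher over all genes, and 4 higher and 1 lower when adjusted over the list alone. The secondary granule and neutrophil list had a median of 0.58 over 11 genes, again above each random list, with S100a8 and Cd177 called higher, and 4 when adjusted over the list alone. Of 13 primary granule and progenitor genes, which mark less mature granulocyte-monocyte cells, Prtn3 fell 2.20-fold, 6 were called lower when adjusted over the list alone, and the median was −0.47. The 16 integrated stress response genes had a median of −0.51, with Asns, the asparagine synthetase gene, called lower at −1.09 ± 0.29 and 6 called lower when adjusted over the list alone. After median centring these medians stood at −0.48 for the Myc list, 0.59 for the macrophage list, 0.74 for the neutrophil list, −0.32 for the primary granule list and −0.36 for the stress response list.

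A separate NSD3 table came from polyA libraries. It names its conditions only q1 and q2, and its labels do not say which is the control, so its folds are given as q2 relative to q1. Whsc1l1 stood at 17.3 FPKM in q1 and 8.85 in q2, a log2 fold of −0.96 ± 0.09. That fall of the targeted gene is the basis used here for setting q2 over q1 beside the direction of a knockdown. The limit of an FPKM above 5 also falls on q1, as on the named controls of the other polyA tables, while q2 reached 1.17. Neither point names the conditions. Calprotectin and granule genes led the genes higher in q2. S100a9 stood at 236 FPKM in q1 and 1087 in q2, a 4.61-fold rise in the authors' deposited table. Lcn2, a siderophore-binding granule protein, was 3.63-fold higher, Ngp 2.95-fold and Camp, the cathelicidin gene, 2.75-fold. Csf1r, the receptor for the macrophage growth factor, was 1.87-fold higher, Irf8, a transcription factor of monocyte development, 2.09-fold, and Itgam, which encodes CD11b, stood at 0.56 ± 0.07. Myc was 1.33-fold lower in q2, at 26.5 against 35.4 FPKM, and Kit, the stem cell factor receptor gene, was 1.38-fold lower.

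In that table the authors called 502 genes higher and 185 lower in q2 among 7697, with 19 and 7 of them at least 2-fold. Median centring gave 413 and 256, and quantile normalization 373 and 297. With standard errors widened until z had a robust spread of 1, an alternative added after seeing the data that also counts real change as error, 180 were higher and 56 lower. The largest rises among named genes were those of S100a9, Lcn2, Ngp, S100a8, Camp, Olfm4, Hck, Lsp1, Lars2, Rmrp, Cd300ld and Tlr13. Rmrp is an RNA without a poly(A) tail, at 6552 FPKM in shRen of the NSR table but 5.13 in q1 and 11.5 in q2, and Lars2 was at 2771, 183 and 430. These levels come from separately normalized tables. The rise of Rmrp may reflect carry-over of RNA without a tail into the polyA libraries, which was not tested. What lies behind that of Lars2 is open. Lars2 also rose in shCHD8, from 23.5 to 55.0 FPKM (log2 fold 1.23), and stood at 0.08, not called, in sgCHD8. The largest falls were those of Tspan12, Fads2, Cercam, Kbtbd7, Mrgpra2b, Mrgpra2a, Dusp2, Whsc1l1, Dio2, Ccr2, Chst13 and Slc19a1, where the copies Mrgpra2a and Mrgpra2b cannot be separated with confidence. Of 23 macrophage and monocyte genes, 18 were called higher and 1, the chemokine receptor gene Ccr2, was called lower in the authors' deposited table. Ccr2 and Lyz2 lost their calls with quantile normalization, as their folds went from −0.84 ± 0.19 and 0.79 ± 0.22 to −0.39 and 0.59. Ccr2 stood at 5.16 FPKM in q1, near the limit of 5, which bounds q1 but not q2. Quantile normalization shrinks falls there by construction. Lyz2, at 1200 FPKM in q1, lay near the top of the table (highest 2920), where rises can shrink too. These lost calls do not weigh the evidence for a change. Adjusted over the list alone, 19 were higher and 1 lower. Of 8 secondary granule and neutrophil genes 5 were called higher, also when adjusted over the list alone, with a list median of 1.47. Of 52 Myc target and ribosome biogenesis genes 8 were called lower, among them Polr1b at −0.51 ± 0.15 and Dkc1 at −0.49 ± 0.12, and 14 when adjusted over the list alone. Of 28 mitosis genes 12 were called lower, including Ccnb1 at −0.62 ± 0.12, and 16 when adjusted over the list alone, while of 31 DNA replication genes 1 was called, Ccne1, which was higher at 0.49 ± 0.14.

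Set side by side, the NSR and polyA tables of NSD3 had log2 folds that correlated across 7405 shared genes with a Pearson r of 0.42, where genes are not independent replicates. Of the genes called in both, 19 were higher in both and 6 lower in both, against 1.45 and 0.413 for independent lists, and 1 was called in opposite directions. A test of the difference between the folds passed for 12 genes (Benjamini-Hochberg q under 0.05), and for 7 with widened standard errors. Myc was among them, with a difference of −0.82 ± 0.21 that lay just inside the threshold (q = 0.0498). Cd177, Il1rn, Kbtbd7, Tspan12 and Stfa2l1 stood higher in the NSR table, and Magoh, Nans, H2-T23, Dnaja3 and Rmrp stood lower. Il1rn, the interleukin-1 receptor antagonist gene, was the one called in both with opposite signs, at 1.44 ± 0.31 in NSR and −0.42 ± 0.06 in the polyA table, and its rise in NSR shrank to 1.07 and lost its call with a pseudocount of 1.

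The second question is what CHD8 loss changes. Chd8 (mm9 chromosome 14, 52817825 to 52857247) fell from 22.7 FPKM in shRen to 10.4 in shCHD8, a log2 fold of −1.13 ± 0.17, and from 22.4 in sgRosa26 to 10.4 in sgCHD8, a log2 fold of −1.11 ± 0.07, in the authors' deposited tables. Whsc1l1 stood at 0.02 ± 0.11 and 0.01 ± 0.06 in these comparisons, and Chd8 stood at −0.28 ± 0.27 in the NSR table of NSD3 and at 0.04 ± 0.11 in the polyA table. With CHD8 loss, several genes of macrophages rose. Cd14, the lipopolysaccharide co-receptor gene, rose 6.24-fold with the hairpins and 2.84-fold with the guides. Spp1, the osteopontin gene, rose 7.76-fold and 2.73-fold, and the secreted matrix protein gene Thbs1 rose 16.5-fold and 2.46-fold. Lyz2 rose from 279 to 1741 FPKM with the hairpins and from 1018 to 2352 with the guides. Itgam rose 1.78-fold and 1.70-fold. Myc fell 1.32-fold and 1.37-fold.

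**Figure D1:**
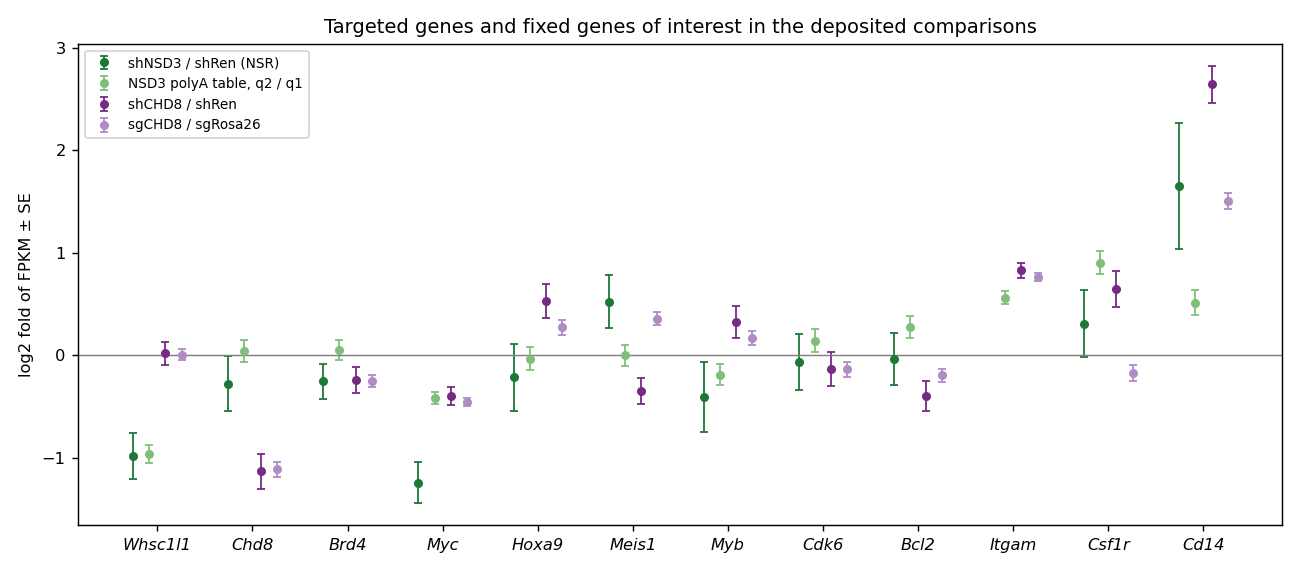
Log2 fold of FPKM (vertical axis) for the 2 targeted genes and 10 further genes fixed in advance, with 1 point per deposited comparison that lists the gene. Bars are 1 standard error as the authors' test statistic implies. Itgam is not listed in the NSR table. Whsc1l1 lies near −0.98 in both NSD3 comparisons and near 0 in both CHD8 comparisons, Chd8 lies near −1.11 in both CHD8 comparisons, and Myc lies below 0 in each of the 4.

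Both CHD8 tables called 521 genes higher and 736 lower, against 184 and 282 for independent lists, and 125 genes were called in opposite directions. The hairpin table alone called 845 higher and 1371 lower among 7800, and the guides gave 1789 and 1681 among 7836. In the hairpin table median centring gave 1093 higher and 925 lower, and quantile normalization 994 and 1020. The guide table gave 1704 and 1761 with centring, and 1643 and 1788 with quantile normalization. Genes called alike in both tables then numbered 617 higher and 564 lower with centring, and 555 and 651 with quantile normalization. Both scalings pull the folds towards an even split by construction. Neither restores genes low in the control that rose, which these tables leave out. Which direction holds more genes therefore depends on the scaling and is not decided here. The log2 folds of the pair correlated across 7603 genes with r = 0.51. Among genes called in both tables, the largest rises by mean fold were those of Thbs1, Spp1, Cd14, Lyz1, Lyz2, Adam8, Ccl4, Stfa3, Lgals3, Lilrb4, Gp49a and Ccl3. The largest falls were those of Cx3cr1, Pccb, Zbtb45, Bex6, Phpt1, Usp11, Hmgn1, Prssl1, Camp, Prmt1, Chd8 and Pcdhgc3. Cx3cr1, the fractalkine receptor gene, fell 9.29-fold with the hairpins and 1.45-fold with the guides. Prmt1, which encodes the main arginine methyltransferase, fell 1.89-fold and 2.62-fold. These counts rest on Cuffdiff's standard errors. If those are widened until the z values of each table have a robust spread of 1, an alternative added after seeing the data that also counts real change as error, 26 genes remain called higher in both tables and 6 lower.

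**Figure D2:**
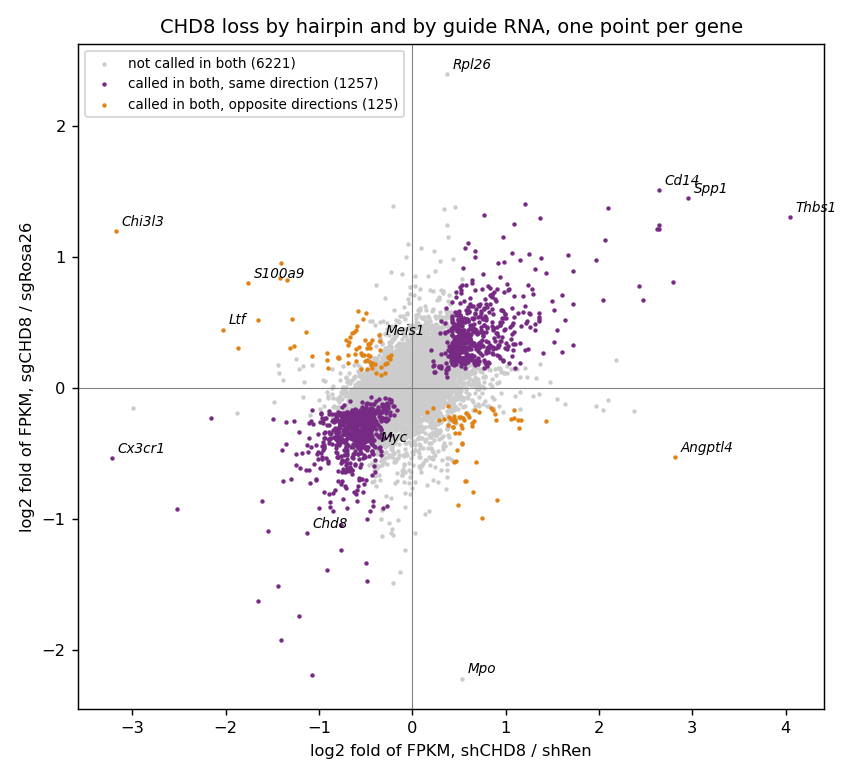
Log2 fold of FPKM for shCHD8 over shRen (horizontal axis) and sgCHD8 over sgRosa26 (vertical axis), with 1 point for each of 7603 genes. Both tables called 521 genes higher and 736 lower, and the 125 called in opposite directions include S100a9, Ltf and Chi3l3 at the upper left.

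Of the fixed lists, the Myc target and ribosome biogenesis genes fell in both CHD8 tables. The authors' deposited tables called 39 of 52 lower with the hairpins, with a list median of −0.53, and 31 of 52 lower with the guides, with a median of −0.23, and none was called higher. Grwd1, a ribosome assembly factor gene, stood at −1.09 ± 0.17 and −0.26 ± 0.08, and Polr1b, which encodes a subunit of RNA polymerase I, at −0.97 ± 0.17 and −0.55 ± 0.08. Of the DNA replication genes 23 of 30 and 21 of 31 were called lower, such as Mcm5 at −0.81 ± 0.18 and −0.37 ± 0.08. Of the mitosis genes 12 of 28 and 21 of 29 were called lower, such as Plk1 at −0.66 ± 0.17 and −0.29 ± 0.07. Each of these medians lay below each of the 10000 random lists. Adjusted over the list alone, the lower calls numbered 42 and 31 for the Myc list, 25 and 21 for replication and 16 and 23 for mitosis.

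Macrophage and monocyte genes rose with CHD8 loss, with 16 of 23 called higher and 3 lower in the hairpin table and 20 of 26 called higher and 2 lower in the guide table. Adjusted over the list alone the counts were 17 and 3 with the hairpins and 21 and 3 with the guides. The list medians were 0.79 and 0.37, above each random list. Each named member of this list stood lower in shRen than in sgRosa26, although these tables were normalized separately. Lyz2 stood at 279 against 1018 FPKM, Lyz1 at 23.3 against 87.5 and Irf8 at 43.1 against 50.6. How far the larger hairpin folds rest on a low shRen level was not tested. Irf8, at −1.10 ± 0.17 and −0.38 ± 0.07, and Cx3cr1, at −3.22 and −0.54, were called lower in both tables. Ctss was called lower with the hairpins, at −0.61, and higher with the guides, at 0.20. Csf1r rose with the hairpins, at 0.65, and stood at −0.17, not called, with the guides. The labels describe 1 sgRosa26 library, so the calls of the guide table have no replicate check on the control side. The shRen control of the hairpin table may also be 1 library, since which libraries stand behind it is not given. All 14 measured p53 target genes were called higher in the guide table, also when adjusted over the list alone, with a median of 0.43, led by Phlda3 at 1.11 ± 0.09, Cdkn1a, the cell cycle inhibitor p21 gene, at 0.90 ± 0.06, and Trp53inp1 at 0.89 ± 0.04. With the hairpins 4 of 11 were called higher and 1 lower, or 6 and 1 when adjusted over the list alone, with Cdkn1a at 1.31 ± 0.15. Among the MLL-fusion target and self-renewal genes, Hoxa9 rose in both tables, at 0.53 ± 0.17 and 0.27 ± 0.07, as did Hoxa10, at 0.57 ± 0.11 and 0.30 ± 0.05. Over this list 2 of 22 were called higher and 7 lower with the hairpins, and 11 of 21 higher and 5 lower with the guides, the same counts as when adjusted over the list alone. Meis1 stood at −0.35 ± 0.13 with the hairpins, a call lost under median centring (−0.27) and quantile normalization (−0.30), and at 0.36 ± 0.07 with the guides. Bmi1, a Polycomb gene, fell 2.25-fold with the hairpins and stood at −0.07 ± 0.08 with the guides. Of the other fixed genes, Brd4 stood at −0.24 ± 0.13 and −0.25 ± 0.06, with only the guide table calling it, and Cdk6 was not called in any of the 4 tables. The apoptosis inhibitor gene Bcl2 stood at −0.40 ± 0.15 and −0.20 ± 0.07, called in both tables, with the hairpin call lost under either scaling (−0.32 and −0.34). Myb stood at 0.32 ± 0.15, not called, and 0.17 ± 0.07, called in the guide table but not after quantile normalization (0.10). Neither was called in an NSD3 table.

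The hairpin and guide comparisons of CHD8 differed in several respects, and the test of the difference passed for 999 genes, 453 of them higher with the hairpins and 546 lower (Benjamini-Hochberg q under 0.05). With widened standard errors it passed for 24. The guide side of each difference rests on 1 sgRosa26 library, as the labels describe no other. The hairpin side may also rest on 1 control library. Which shRen libraries stand behind it is not given, and 1 shRen title lacks a replicate number, as the shCHD8 titles do. Secondary granule and neutrophil genes fell with the hairpins and rose with the guides. Of 12 measured, 8 were called lower in shCHD8, and 10 were called higher and 1, Camp, lower in sgCHD8. Adjusted over the list alone, 2 were higher and 8 lower in shCHD8, and the counts in sgCHD8 did not change. For 10 the difference itself passed. S100a9 went from 2321 to 686 FPKM with the hairpins and from 3202 to 5561 with the guides, Ltf, the lactoferrin gene, stood at −2.03 ± 0.17 and 0.44 ± 0.07, and Chi3l3 at −3.17 ± 0.20 and 1.19 ± 0.08. The rises of S100a8 and S100a9 with the guides turned to −0.085 and −0.11 under quantile normalization. That scaling works by rank and leaves genes at the top of a table, such as S100a9, little room to rise. Mpo, the myeloperoxidase gene of primary granules, fell 4.66-fold with the guides and stood at 0.53 ± 0.27, not called, with the hairpins. Ctsg, the cathepsin G gene, rose 4.13-fold with the hairpins and stood at −0.17 ± 0.10 with the guides.

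Cholesterol synthesis and integrated stress response genes also differed between the hairpins and the guides. Of 23 cholesterol synthesis genes, the authors' deposited tables called 13 higher in shCHD8 and 9 lower in sgCHD8, with list medians of 0.44 and −0.14, and 15 higher and 8 lower when adjusted over the list alone. Sc5d stood at 1.01 ± 0.17 and 0.16 ± 0.08, and Nsdhl at 0.88 ± 0.17 and −0.20 ± 0.08. Of the integrated stress response genes, 9 of 18 were called higher in shCHD8 and none lower, while 4 of 16 were called higher and 9 lower in sgCHD8. Adjusted over the list alone, 10 were higher in shCHD8, and 4 higher and 10 lower in sgCHD8. Asns rose 1.87-fold in shCHD8 and fell 1.82-fold in sgCHD8, and Ddit3, which encodes CHOP, rose 2.93-fold and 1.35-fold. The difference passed for 14 of the cholesterol genes and 11 of the stress response genes, each higher with the hairpins. The largest differences for single named genes were those of Angptl4, Thbs1, Mpo, Impdh1 and Ctsg, higher with the hairpins, and of Chi3l3, Mgl2, Cx3cr1, S100a9 and Ltf, lower.

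**Figure D3:**
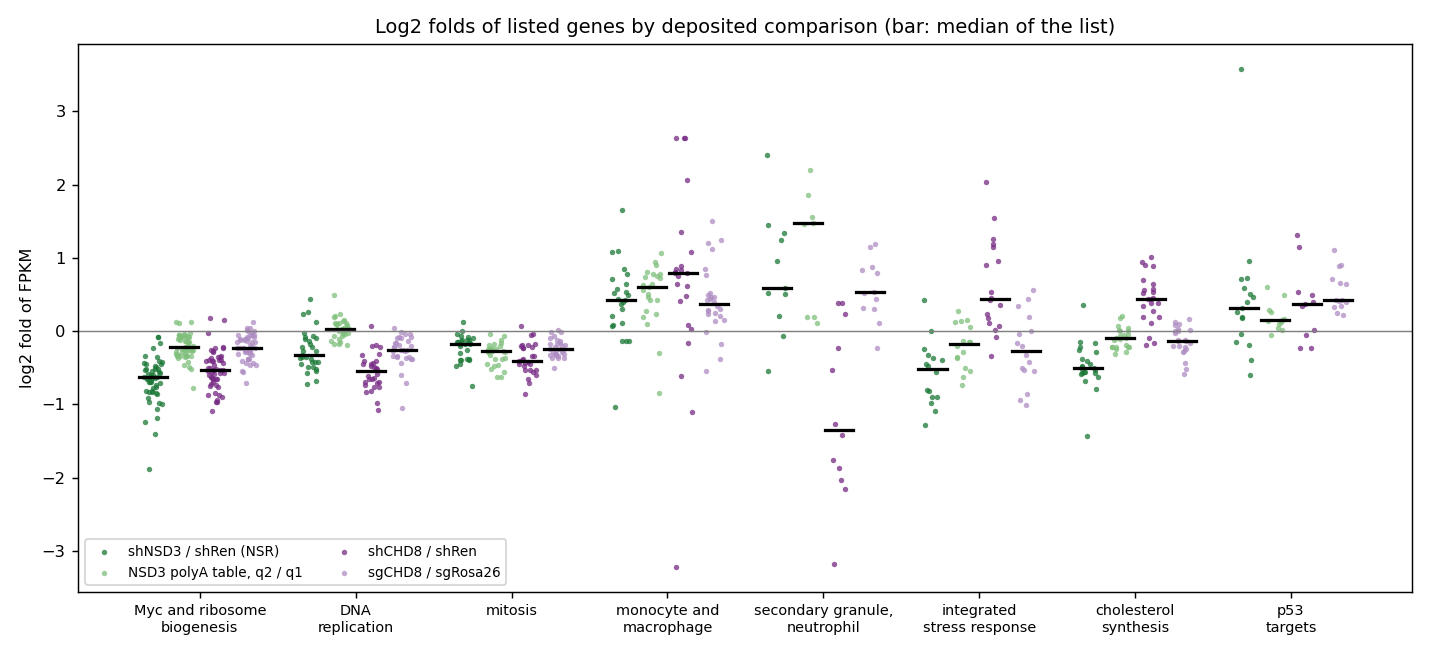
Log2 fold of FPKM (vertical axis) for each measured gene of 8 fixed lists, with 1 point per gene, 1 colour per deposited comparison and a bar at the list median. Myc target and ribosome biogenesis genes have medians below 0 in each comparison, from −0.63 in the NSR table to −0.22 in the polyA table, while secondary granule and neutrophil genes have a median of −1.35 in shCHD8 and of 0.53 in sgCHD8.

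The third question is how far the effects of NSD3 and CHD8 loss resemble each other. Myc fell by 1.24 ± 0.20 on the log2 scale in the NSR table and by 0.40 ± 0.09 and 0.45 ± 0.04 with CHD8 hairpins and guides, and stood at −0.42 ± 0.06 in q2 relative to q1, where the control is not named. With that table read as q2 relative to q1, the authors' deposited tables called 3 genes lower in all 4, namely Myc, Bzw2 and Chdh, and 11 genes higher in all 4, among them Stfa2l1, Stfa3, Lyz1, Lyz2, Ccl3, Gp49a and Lilrb4. Chdh is named here only after its values were seen. With a pseudocount of 1 the calls of Bzw2 and Lyz2 in NSR ended. The fold of Bzw2 went from −1.29 to −1.08, while that of Lyz2 hardly moved (1.07 ± 0.29 to 1.06), and its call ended through the adjustment over the other genes. The log2 folds of the NSR table correlated with those of sgCHD8 at r = 0.41 over 7492 genes and with those of shCHD8 at r = 0.27 over 7473. For q2 relative to q1 the values were 0.43 over 7361 and 0.28 over 7337. None of the condition 1 values was identical between any pair of tables. Separately normalized tables could give the same library different values, so this does not decide whether control libraries were shared. A library was made either with NSR primers or from polyA RNA, so the NSR table shares none with the polyA tables. Whether libraries of both kinds came from the same RNA is not given in the sources used here. Between shCHD8 and the polyA NSD3 table, the log2 ratios of the condition 1 values had an SD of 0.52 across genes. Between shRen and sgRosa26 of the CHD8 tables, which were different libraries, it was 0.23. A difference by 1 factor gives no spread across genes, so this argues against the same single library behind both. Part of the likeness may still come from pools that share some shRen libraries. The control of the sgCHD8 table was sgRosa26, so shared shRen libraries do not account for its correlations with the NSD3 tables, which were the higher ones.

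Of the genes called in NSR and sgCHD8, 21 were higher in both and 11 lower in both, against 5.01 and 4.01 for independent lists, and 1 was opposite. With shCHD8 the counts were 12 and 6, against 1.83 and 3.24, and 4 were opposite. For q2 relative to q1 with sgCHD8, 303 genes were higher in both and 106 lower in both, against 111 and 35.3, and 40 were opposite, and with shCHD8 the counts were 186 and 67, against 50.6 and 27.7, and 78 were opposite. Of the genes called alike in both CHD8 tables and in q2 relative to q1, 154 were higher and 57 lower. NSR gave 115 of the 140 higher ones that it listed a positive fold (82.1%, against 33.5% of all its genes), and 50 of its 53 lower ones a negative fold (94.3%, against 66.5%).

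Effects of NSD3 and CHD8 loss also differed. The test of the difference passed for 148 genes between NSR and shCHD8, 33 higher in NSR and 115 lower, and for 23 between NSR and sgCHD8, 5 higher and 18 lower. These pairs also differ in library protocol, NSR primers against polyA RNA, which cannot be told apart from the target. The median log2 fold was −0.15 in NSR, −0.08 in shCHD8 and 0.01 in sgCHD8, a shift towards lower values in NSR. Against shCHD8, the largest named differences were Cx3cr1, Mgl2, Olfm4, Cyp4f18 and S100a9, higher in NSR, and Thbs1, Angptl4, Impdh1, Ctsg and P2rx4, lower. Filtering at a mean FPKM of 5 lowered the count of 148 to 96, quantile normalization lowered it to 97, and widened standard errors lowered it to 25. Between q2 relative to q1 and the CHD8 tables, 1031 genes differed for shCHD8 and 766 for sgCHD8. DNA replication genes showed such a difference as a group in the polyA table, with a median of 0.03 in q2 relative to q1 (−0.018 with quantile normalization) and of −0.55 and −0.26 in the CHD8 tables, and the difference passed for 18 of 30 and 7 of 31 members. In the NSR table, whose median gene lay at −0.15, the DNA replication median was −0.33. Its median differences were 0.24 from shCHD8, above each random list, and −0.051 from sgCHD8, above 99.3% of them. The difference passed for 1 of 30 members against shCHD8 and for 0 of 31 against sgCHD8. In simulation the test against shCHD8 recovered 20.8% of changes of 1 and 0.14% of changes of 0.5. These rates need not hold in the real data. Few passes therefore do not show that the members moved alike. Other lists also differed from shCHD8. Median differences of secondary granule genes were 2.61 for NSR (6 of 10 passed) and 2.49 for q2 relative to q1 (6 of 8). For cholesterol synthesis genes they were −0.90 (8 of 23) and −0.55 (10 of 23), and for stress response genes −0.86 (5 of 16) and −0.66 (9 of 16). Against sgCHD8 no member of these lists passed in NSR, and the q2 to q1 medians were 0.81, 0.026 and −0.033.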

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

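The tests of the shRen level in neutrophil genes, of both kinds of scaling and of the size of the folds were chosen only after the result, or the list medians and table shift it rests on, had been seen, while those of the shRen level in stress response and cholesterol genes and of exchanged standard errors were written first. Tests with a median centred table and a bound of 0.5 on the shRen level came first and left 3 questions undecided. Quantile normalization, the wider bound and the differences after quantile normalization were added after that, and both sets are given. The rule that sets the size of the folds aside when a table's spread is mostly error was also added with its values known.

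The fold differed between shCHD8 and sgCHD8 for 999 genes by the test of the difference, and between the NSR and polyA tables of NSD3 for 12. With widened standard errors, added after seeing the data and also counting real change as error, these counts were 24 and 7. Each gene below was picked out because that test passed with calls in opposite directions, and each list because its median difference lay outside the middle 95% of random lists with medians of opposite sign.

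Of 12 secondary granule and neutrophil genes, 8 were called lower with the CHD8 hairpins, and 10 were called higher and 1 lower with the guides. The median difference between the log2 folds was −1.76. Chi3l3 differed by −4.37, S100a9 by −2.55, Ltf by −2.47, Olfm4 by −2.36, S100a8 by −2.26, Ngp by −2.17 and Cd177 by −1.06. The median log2 ratio of shRen to sgRosa26 over the 12 genes was −0.29, with a bootstrap interval from −0.47 to 0.49. Intervals here and below resample the genes of a list, which need not be independent, and hold no spread between libraries. For these pooled values the ratio argues against an shRen level high enough to give the whole difference, which would need at least 1.5. It leaves open that shRen stood somewhat high in part of these genes. Levels of separately normalized tables are set side by side here. After median centring the list median in shCHD8 was −1.27, with an interval over its mixed members from −1.87 to 0.083, which by itself leaves scaling by 1 factor undecided. Quantile normalization cancels any 1 factor and also moves genes singly. After it 8 of 12 were called lower in shCHD8, and the median difference between the tables was −1.51 (interval −2.11 to −0.85). This argues against scaling of either kind as the whole of the difference. In sgCHD8 the higher calls went from 10 to 8. S100a8 and S100a9 turned to −0.085 and −0.11, while their differences were −1.92 and −1.97 after it. Quantile normalization works by rank and leaves genes at the top of a table little room to rise. S100a9 ended above the highest sgRosa26 value of 3978 FPKM, so its turn was largely built in. For these genes this scaling therefore cannot tell what gave the rise. Median centring moves the folds of sgCHD8 by only 0.01. The reagent, the time (48 hours against 4 days), off-target effects and the maturation of the cultures differ or can differ between the arms, and CHD8 loss itself may act differently over time. None of these was tested.

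Cholesterol synthesis genes (median difference 0.55) and integrated stress response genes (0.68) stood higher with the hairpins than with the guides, although stress response genes went both ways with the guides. A low shRen level would give a ratio to sgRosa26 below 0. The median log2 ratio was 0.11 for the cholesterol genes (interval over genes 0.079 to 0.25) and 0.26 for the stress response genes (0.20 to 0.32). For these pooled values this argues against a low shRen level, with no spread between libraries weighed. After median centring the list medians in shCHD8 were 0.52 for the cholesterol genes (0.36 to 0.65), which argues against scaling by 1 factor, and 0.52 for the stress response genes (0.25 to 1.13), which missed the bound of 0.3 set first. After quantile normalization, which cancels any 1 factor, 14 cholesterol genes and 10 stress response genes were called higher in shCHD8, and the median differences between the tables were 0.61 (0.50 to 0.75) and 0.74 (0.50 to 1.02). This argues against scaling of either kind as the whole of these differences. Off-target effects of the reagents, the state of the culture at harvest, and an effect of CHD8 that depends on time may each contribute, and none was tested. A general response to hairpins or doxycycline would lie on both sides of the shCHD8 fold, since shRen was also an induced hairpin.

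The tables called very different numbers of genes, 55 in NSR against 3470 in sgCHD8. When each gene of sgCHD8 was given its NSR standard error, 25 of 7492 shared genes were called, against 3268 with its own, so the gap can come from Cuffdiff's standard errors. Whether real folds were larger in sgCHD8 is open. The robust SD of its log2 folds was 0.667 times that of NSR, but over these genes the NSR spread was no wider than its standard errors (robust SD of z 1.00, against 2.94 in sgCHD8). It is mostly estimation error, so the ratio decides nothing. Why the standard errors differ is open as well.

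Ribosomal protein genes had a median difference of 0.36 between shCHD8 and sgCHD8, and primary granule and progenitor genes one of 0.22, where quantile normalization brought the primary granule median in shCHD8 to 0.18, inside the range of random lists. Angptl4 differed by 3.35, Dusp2 by 1.33 and Meis1 by −0.70 between shCHD8 and sgCHD8. The fall of Meis1 in shCHD8 (−0.35 ± 0.13) lost its call with median centring (−0.27), quantile normalization (−0.30) and a pseudocount of 1 (−0.32). That of Dusp2 in sgCHD8 (−0.24 ± 0.10) lost its call with a pseudocount of 1 (−0.21). With the pseudocount both folds moved by less than their standard error, and the calls, at q-values of 0.0259 and 0.0363 as deposited, ended. Il1rn differed by 1.86 between the NSR and polyA tables of NSD3, and its fold in NSR went from 1.44 ± 0.31 to 1.07 with a pseudocount of 1, which ended its call.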

How the results depend on the processing

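Widened standard errors, q-values recomputed over the rows and the limit on shRen FPKM were chosen after seeing the data. No paired analysis was possible because the tables give 1 value per condition and no value per library. For the same reason leaving out a library, other splits of the samples, limma without trend or with a shared spread, a fit without the table term, and camera with an estimated correlation were not run, and depth could not be weighed. The cause of a move was not tested, except that wider errors call fewer genes by construction and a filter leaves fewer genes. A pseudocount with the standard errors kept also lowers z by construction, most for low genes.

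With widened standard errors q2 over q1 had 180 genes higher and 56 lower, shCHD8 79 and 50, sgCHD8 82 and 66, and both CHD8 tables together 32, as 26 higher and 6 lower. The differences then numbered 25 for NSR minus shCHD8, 7 for NSR minus polyA and 24 for guides against hairpins. Lower genes in NSR, 27 as deposited, numbered 41 at a mean FPKM of 5, 46 at an shRen FPKM of 5, 12 with median centring and 8 with quantile normalization, and q2 over q1 had 297 lower with quantile normalization. NSR minus shCHD8 gave 96 with the filter and 97 with quantile normalization. Counting every gene past 2-fold, called or not, NSR had 131 higher and 215 lower as deposited, 22 and 31 with a pseudocount of 1, 17 and 31 with the filter, and 119 lower with median centring, and shCHD8 had 76 lower as deposited and 49 with quantile normalization. The correlation of NSR and q2 over q1 was 0.451 with a pseudocount of 1 and 0.517 with the filter, and with the filter NSR correlated at 0.335 with shCHD8 and 0.499 with sgCHD8.

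Quantile normalization turned S100a8 and S100a9 in sgCHD8 to −0.085 and −0.11, and the filter turned the p53 list in NSR to −0.044. Whsc1l1, Chd8 and Myc kept direction and call in the tables that called them under both pseudocounts and both scalings. The other counts computed stayed within 1.5 times of those reported. Among named genes and lists, 23 results lost their call or left the outer range of random lists with a pseudocount of 1, 8 with 0.1, 10 with median centring, 16 with quantile normalization and 1 with the filter.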

Other observations

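Several fixed lists belong to no comparison above. Cytosolic ribosomal protein genes had medians of −0.47 in NSR, −0.06 in q2 relative to q1, 0.21 in shCHD8 and −0.16 in sgCHD8. The authors' deposited tables called none of 65 in NSR (6 lower when adjusted over the list alone) and none of 68 in q2 relative to q1, 2 higher and 1 lower in shCHD8, and 2 higher and 31 lower in sgCHD8. One of the higher ones, Rpl26, went from 21.6 to 113 FPKM with the CHD8 guides and stood at 0.37 ± 0.21 with the hairpins. Ribosomal protein genes have many processed copies, so these values are uncertain. Primary granule and progenitor genes had 5 of 13 called higher and 1 lower in shCHD8, 2 higher and 4 lower in sgCHD8, and 1 higher and 2 lower in q2 relative to q1. Elane, the neutrophil elastase gene, was among the lower ones in each of these 3 tables, at −0.74 ± 0.22, −0.85 ± 0.09 and −0.49 ± 0.14.

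Of the BRD4, NSD and CHD family genes, Whsc1 (NSD2) fell with CHD8 loss, at −0.48 ± 0.09 and −0.26 ± 0.04, and stood at −0.17 ± 0.18 in NSR and 0.00 ± 0.05 in q2 relative to q1. Over that list 5 of 15 were called lower in shCHD8, 7 lower and 1 higher in sgCHD8, and only Whsc1l1 in each NSD3 table. Of 6 interferon response genes listed in each polyA table, 2 were called higher in shCHD8, and 4 higher and 1 lower in sgCHD8, and none was called in q2 relative to q1 or among the 17 listed in NSR. Immediate-early genes had 4 of 7 called higher in shCHD8, 3 of 8 higher and 1 lower in sgCHD8, 2 of 8 higher and 1 lower in q2 relative to q1, and none of 14 in NSR. Of the MLL-fusion list 1 of 21 was called in NSR, Myc, and 2 of 22 were higher and 3 lower in q2 relative to q1. The MLL-fusion list median in NSR was −0.066, and median centring turned it to 0.088. Of p53 targets none of 17 was called in NSR (1 higher when adjusted over the list alone), where the median was 0.31, but −0.044 over the 7 members left by the filter at a mean FPKM of 5, and 2 of 12 were called higher in q2 relative to q1, Cdkn1a and Trp53inp1. Of DNA replication and mitosis genes none of 31 and none of 27 was called in NSR, with medians of −0.33 and −0.17, close to those of random lists for mitosis. Of integrated stress response genes 6 of 16 were lower in q2 relative to q1, and of 23 cholesterol synthesis genes none was called in either NSD3 table. In NSR 22 of the 23 cholesterol genes lay below 0, with a median of −0.50 (−0.35 after median centring), and in q2 relative to q1 16 did, with a median of −0.099. Both medians lay below the middle 95% of random lists.

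Markers of other cell types were mostly outside the tables. Of 13 mast cell and basophil markers 5 were listed in sgCHD8, with Cpa3, Gata2 and Hdc called higher and Kit lower, and 4 in shCHD8, with Gata2 called higher and Hdc lower, and 4 in q2 relative to q1, with Kit called lower, and none of 6 was called in NSR. Of 20 erythroid and megakaryocyte markers 3 were listed in sgCHD8, with Tfrc and Gfi1b called lower, 2 in shCHD8, with Nfe2 called higher and Tfrc lower, and 2 in each NSD3 table, with none called. Of 22 lymphoid markers shCHD8 listed 1, Nkg7, called lower, NSR listed 2, with none called, and the other tables none. Of 16 Wnt target genes 4 were listed in NSR and 2 in each of the others, with Ccnd1 called higher in q2 relative to q1 and Rnf43 lower in shCHD8. Of the replication-dependent histone genes the polyA tables listed only Hist1h4i, in shCHD8, at −0.37 ± 0.26.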
